A study of Mus musculus with 6 samples.

How the data were processed

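Polyadenylated RNA was sequenced from the dissected epicardium and subepicardium of mouse hearts at embryonic day 16.5 (E16.5). Per the labels' protocols, 3 libraries came from wild-type embryos, called control here, and 3 from embryos lacking Meis1 and Meis2 in cells with a history of WT1-Cre activity, called dKO. Each library was a pool of 2 hearts of 1 genotype, made from 40 ng of total RNA with a kit that is not stated to keep the strand of the RNA. Which exons were removed, and whether the control embryos carried the Cre, is not given in the sources used here. Libraries keep the numbers of their titles (control 1, 2 and 4, dKO 1, 2 and 3). Numbers 1 and 2 occur in both groups, and nothing in the labels says that they pair the pools.

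Per the submitters' processing notes, adapters were removed with cutadapt and transcripts were quantified with RSEM 1.3.1 on the GRCm38 build. The annotation release, the later normalization and the filter on genes are not given in the sources used here. The deposited table holds a normalised signal for 14549 genes in 6 libraries, on a linear scale. All 87294 values equalled a whole number of reads plus 0.5, per 1e6 reads of a scaled library size, within a tolerance of 0.01 reads. The scaling factors obtained this way differed from recomputed TMM factors by at most 1.6e-15. All values below are therefore called normalised read counts, on a scale of reads per 1e6. The recovered totals, which cover only the genes in the table, ran from 13146322 to 20635676 reads per library, and 1 read corresponded to 0.0487 to 0.0740 on this scale.

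Genes at 1 or more in at least 3 libraries were to be kept; all 14549 met this. The control and dKO libraries were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a trend) on log2 of the value plus 1, a scale that understates the change of genes with low values. P-values were two-sided and adjusted over all 14549 genes by the Benjamini-Hochberg method, with a threshold of 0.05. Every log2 change is dKO minus control, and errors are SD over the 3 libraries of a group or the standard error (SE) of the fit. No covariate was used, and replicates are pools, so spread between single hearts was not measured. For Meis1 and Meis2 an exact two-sided permutation test was added, whose smallest possible p with 3 against 3 libraries is 0.1. Data for 14170 genes were simulated from the deposited values, with 100 genes changed 2-fold and 100 changed 4-fold. Of these, 41 and 72 were recovered, and 10 unchanged genes were called. The share of changed genes was far lower there than the share called in the data (3205 of 14549), so the recovered shares need not hold for the data.

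Gene lists (29) were fixed from textbook knowledge before the data were examined, as were the tests, the threshold and the rule for named genes. They cover cell types (epicardial and mesothelial, fibroblast and matrix, mural, endothelial, arterial, venous, lymphatic, neuronal, Schwann, cardiomyocyte, macrophage, erythroid, other organs), transcription factors (TALE and Hox, cardiac), epithelial-to-mesenchymal transition, and signalling (retinoic acid, TGF-beta and BMP, Wnt, FGF, angiogenic factors, axon guidance). They also cover cell cycle, cyclin-dependent kinase inhibitors with p53 targets, glycolysis with hypoxia, interferon, immediate early genes, mitochondrially encoded genes and sex-linked genes. The 28 lists with at least 3 measured genes were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation was run beside it, and for gene groups added later without a variance trend. So was fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. In 10 simulated runs the shifted list (18 genes, 2-fold) was called 10 times, and 0 of 270 unshifted lists were called. The simulated genes were independent of one another, so these runs do not test the preset correlation. In the data the estimated correlation ran from -0.18 (Schwann list) to 0.96 (mitochondrially encoded list).

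Named genes were Meis1 and Meis2; the 8 genes with the largest change in each direction among those past the threshold, with groups that did not overlap and a larger group mean of at least 5; and from each list up to 4 members with the smallest p, or 2 of the highest expression where none passed. Predicted models, pseudogenes, histone, immunoglobulin and ribosomal protein genes were excluded from the 8. Other genes named, such as Wt1, Podxl or Prox1, were chosen after their values were seen. The result of 1 gene is not reported here. Identifiers were looked up in GENCODE M21, where 14530 of 14549 were found and 14272 carried the same symbol. Exonic overlap with other genes was taken from the same annotation, since without strand information reads in an overlap can belong to either gene.

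Alternatives covered scaling, pseudocounts of 0.5 and 5, a filter at 5, thresholds, variance models, library weights, the number in the title as a block, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Further alternatives were chosen after seeing the data: leaving out control 1 and dKO 1 together, removing mitochondrially encoded genes, the mean of the cardiomyocyte list or the sex of each pool as a covariate, log2 of the deposited values, and limma voom. The mean of the cardiomyocyte list, called the cardiomyocyte score, separated the genotypes without overlap. Within the groups its trend rested largely on control 1. A call lost with this covariate therefore does not show that the change follows from the share of myocardium. Figures were drawn with matplotlib 3.10.9.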

Results

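The data describe the RNA of epicardium and subepicardium from E16.5 mouse hearts in 3 control and 3 dKO pools. Recovered read totals were 14977143, 15395078 and 15562385 in control 1, 2 and 4, and 18323035, 13146322 and 20635676 in dKO 1, 2 and 3. Mitochondrially encoded genes held 5.99%, 8.80% and 10.4% of the signal in the controls and 19.9%, 11.3% and 12.4% in the dKO pools. The mean log2 value of the cardiomyocyte list was 6.81, 7.92 and 7.97 in the controls and 9.44, 9.12 and 9.17 in the dKO pools. The first principal component held 61.9% of the variance and separated the genotypes, with control 1 (-59.3) farther out than control 2 (-35.9) and control 4 (-34.5). Control 1 had 41 genes at least 4-fold above and 24 at least 4-fold below the mean of the other controls, and dKO 1 had 25 and 38. Among the genes higher in control 1 were Hoxa5 (40.6 against 1.76 and 2.76 in controls 2 and 4) and Isl1 (17.1 against 1.37 and 1.11). The genotypes also differed in the sex of the pools: the Y-linked Ddx3y exceeded Xist, the RNA of the inactive X, in 1 of 3 control pools (control 4) and in 2 of 3 dKO pools (dKO 1 and dKO 2).

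The comparison of dKO with control addresses how loss of both Meis genes, which encode homeodomain transcription factors of the TALE class, affects expression in this tissue. Meis2 was lower in 3 of 3 dKO pools and Meis1 was not. Meis2 (ENSMUSG00000027210, GRCm38 chromosome 2, 115863064 to 116065839) had a normalised read count of 78.34 ± 12.995 (SD, n = 3) in controls and 41.3 ± 5.59 (SD, n = 3) in dKO pools, 52.7% of the control mean. The Meis2 log2 change was -0.90 with an SE of 0.16 (limma adjusted p = 0.0035; exact permutation p = 0.1, the smallest possible). Meis1 (ENSMUSG00000020160, chromosome 11, 18879817 to 19018985) had 77.8 ± 24.8 (SD, n = 3) in controls and 65.9 ± 7.82 (SD, n = 3) in dKO pools, 84.6% of the control mean. Its log2 change was -0.20 with an SE of 0.20 (limma adjusted p = 0.521, exact permutation p = 0.7). Meis1 was 106 in control 1 and 63.6 and 63.4 in controls 2 and 4; its log2 change was 0.05 without control 1, -0.32 without control 2, -0.32 without control 4 and -0.12 without dKO 1. These values cover all exons of each gene, so they do not measure the deleted part, and 9.8% of the exonic bases of Meis1 overlap the gene Gm37818. Neither gene passed with the cardiomyocyte score as a covariate, with a Meis2 change of -0.65 (limma adjusted p = 0.504) and a Meis1 change of 0.92 (limma adjusted p = 0.146).

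**Figure D1:**
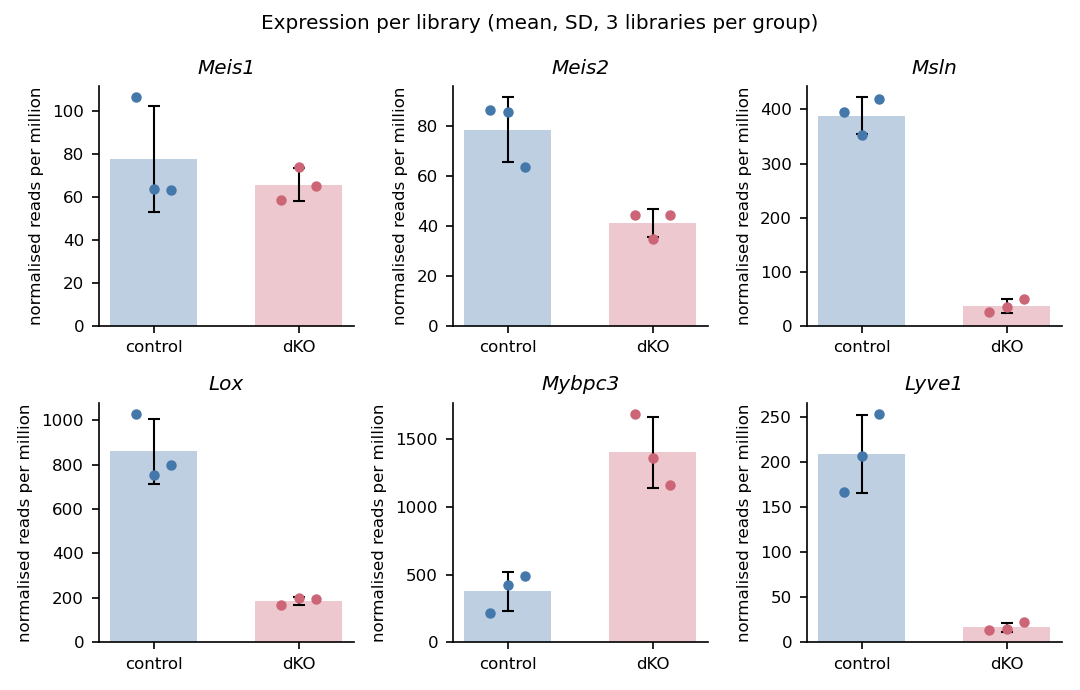
Normalised read counts (reads per 1e6, linear axes from 0) of 6 genes in each control (blue) and dKO (red) library; bars are means and error bars SD over 3 libraries. Meis2 lies at 63.3 or above in controls and at 44.5 or below in dKO pools, while the Meis1 values of the groups overlap.

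In the dKO pools 18 of 19 epicardial and 6 of 8 lymphatic genes were lower, and 18 of 20 cardiomyocyte and 8 of 12 arterial genes were higher. With predicted genes set aside, the largest rise was that of Thbs4, which encodes a matrix thrombospondin. Thbs4 (chromosome 13, 92751590 to 92794818) rose from 10.005 ± 2.05 to 116 ± 22.1 (log2 change 3.41, SE 0.19, limma adjusted p = 5.3e-06). Lrrn4, a mesothelial membrane protein gene (chromosome 2, 132868305 to 132880891), fell from 232 ± 73.4 to 4.92 ± 1.34 (log2 change -5.28, SE 0.24, limma adjusted p = 1.9e-06). C3, the central complement component (chromosome 17, 57203970 to 57228136), fell from 113 ± 20.1 to 1.74 ± 0.931 (log2 change -5.41, SE 0.25, limma adjusted p = 1.9e-06). Of 14549 genes, 3205 (22.0%) changed, 1427 upward and 1778 downward; 603 rose and 992 fell at least 2-fold. On the scale of log2 of the value plus 1, which understates the change of genes with low values, 2 rose (Thbs4 and the predicted gene Gm15920, chosen after its values were seen) and 86 fell at least 8-fold; with edgeR on the recovered reads 26 rose and 246 fell by as much. The groups did not overlap for 5871 genes (40.4%, against 10% by chance), among them 3189 of the 3205 changed genes.

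The other genes with the largest rises, predicted genes again set aside, were Cxcr4, the receptor of the chemokine Cxcl12 (4.31 to 34.7, log2 change 2.81), the secreted collagen-related Cthrc1 (20.1 to 101.2, 2.59), Ctnna2 (2.03 to 16.4, 2.53), the calcium release channel gene Ryr3 (3.43 to 22.5, 2.49), Plekhh1 (2.03 to 14.8, 2.34), the meiotic cohesin gene Rec8 (1.299 to 10.6, 2.34) and the natriuretic peptide gene Nppa (2.58 to 20.6, 2.33). Cthrc1 was 40.7 in control 1 against 8.14 and 11.4 in the other controls, and Ryr3 was 5.84 in control 2 against 1.64 and 2.83. Besides Lrrn4 and C3, the largest falls were those of the lymphatic chemokine gene Ccl21a (82.7 to 0.436, log2 change -5.72), the mast cell proteases Cma1 (87.4 to 1.87, -4.93) and Cpa3 (127 to 3.72, -4.76), the lymphatic gene Mmrn1 (106 to 3.38, -4.60), the stress-responsive Nupr1 (33.1 to 0.496, -4.55) and the matrix gene Efemp1 (344 to 15.1, -4.45). The fold of Ccl21a is uncertain, since near-identical gene copies share its reads, and in dKO pools it rests on 7, 0 and 16 reads. That of Nupr1 rests on 0, 9 and 15 reads there. Other genes share exonic bases with Nppa (61.5%), Plekhh1 (14.8%) and Ryr3 (4.8%), so their reads are not wholly their own. The same holds for genes named further on, with over 10% of exonic bases shared in Tagln (62.4%), Rarb (34.1%), Cdkn1c (30.7%), Spry1 (24.4%), Bnip3 (22.3%), Tbx18 (20.6%), Hand2 (19.6%), Uchl1 (18.1%), Sox17 (16.8%), Smtn (16.3%), Sfrp2 (16.1%), Pkm (15.3%), Csf1r (15.1%), Hoxa2 (15%), Ccna2 (12.5%) and Xist (11%).

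The number of genes that rose was 910 without dKO 2 and 898 without dKO 3. With control 1 and dKO 1 both left out, 3169 genes changed, 2564 of them shared with the 3205, and with the cardiomyocyte score as a covariate 285 changed, 222 of them shared.

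Epicardial and mesothelial markers fell almost as a whole: 18 of 19 were lower in the dKO pools and 0 higher (adjusted over the list alone, 18 lower), with a median log2 change of -2.97. Besides Lrrn4, the list included Rspo1, a secreted Wnt agonist (65.4 to 3.71, log2 change -3.81), the mesothelial surface gene Msln (389 ± 33.5 to 36.9 ± 12.2, -3.41) and the uroplakin gene Upk1b (232 to 28.9, -2.97). Among transcription factor genes of the list, Bnc1 fell from 109 to 9.44 (-3.43), Wt1 from 173 to 67.6 (-1.302), Tcf21 by 1.22 and Tbx18 by 0.92 on the log2 scale. Podxl did not pass, at 192 in control and 161 in dKO pools (-0.12, limma adjusted p = 0.809). For the list, camera gave an adjusted p of 1.02e-19, and adjusted p = 0.157 with an estimated correlation. Per library, the median of the list against the control mean was 0.39, -0.07 and -0.18 in controls and -3.22, -3.19 and -2.64 in dKO pools. With the cardiomyocyte score as a covariate 11 members fell and 1 rose (median -2.41, camera adjusted p = 4.58e-19).

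Fibroblast and matrix genes were also lower, 17 of 22, with 0 higher (adjusted over the list alone, 19 lower and 1 higher) and a median of -1.24. They included the collagen cross-linking enzyme Lox (860 to 186, log2 change -2.19), the matrix proteins Fbln2 (416 to 85.2, -2.28) and Lum (465 to 144, -1.67), and the surface marker Thy1 (28.9 to 4.70, -2.37). The 5 that did not pass were Mfap5 (-1.52), Ddr2 (-0.81), Fn1 (-0.18), Col6a3 (0.16) and Postn (0.42). Camera gave the list an adjusted p of 2.05e-10, and adjusted p = 0.246 with an estimated correlation; with the cardiomyocyte score as a covariate 8 members fell and the median was -1.24 (camera adjusted p = 1.21e-06). Of 16 genes of epithelial-to-mesenchymal transition and adhesion, 7 fell, 2 rose and 7 did not pass (adjusted over the list alone, 7 lower and 2 higher), with a median of -0.55. The mesenchymal transcription factor genes Twist2 (5.93 to 0.356, -2.33, and -4.12 with edgeR) and Snai2 (-0.84) and the mesenchymal cadherin Cdh11 (-1.98) fell, and so did the epithelial cadherin Cdh1 (-1.88, and -3.40 with edgeR). The N-cadherin gene Cdh2, which cardiomyocytes also express, rose from 334 to 859 (1.39), and the fibronectin receptor subunit Itga5 rose by 0.84. Camera gave this list an adjusted p of 0.0164, and adjusted p = 0.254 with an estimated correlation. That call was lost with a filter at 5 (camera adjusted p = 0.146) and with the cardiomyocyte score as a covariate (median -0.50, camera adjusted p = 0.324), and 46.5% of the exonic bases of Twist2 overlap another gene.

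**Figure D2:**
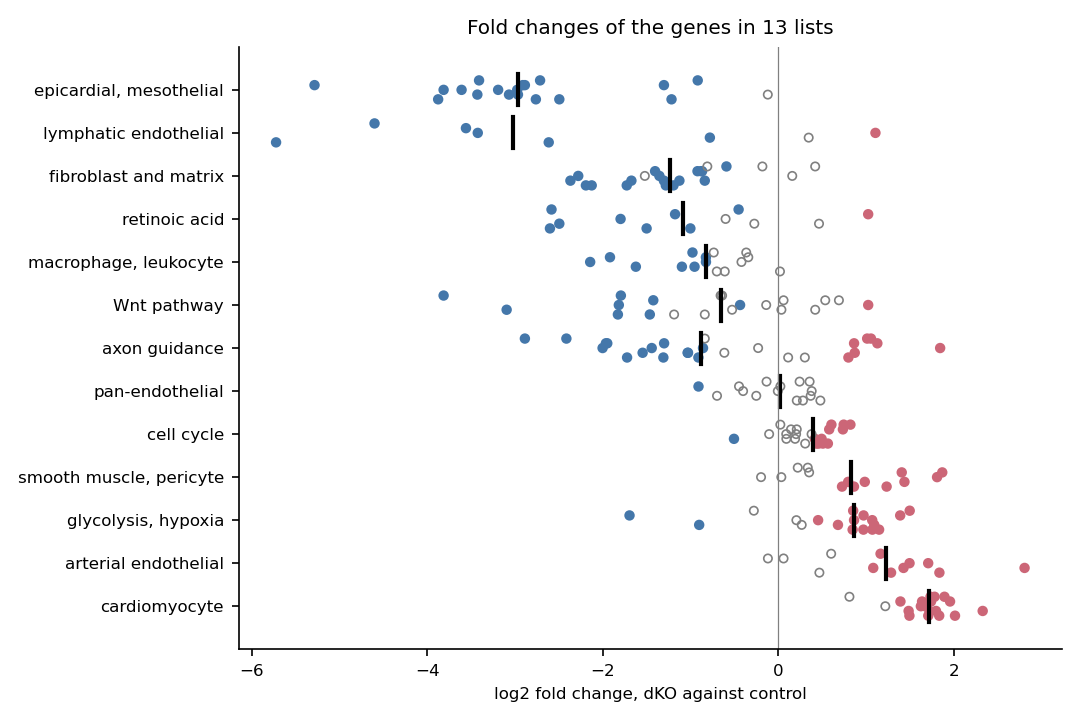
Log2 change (dKO minus control) of each measured member of 13 gene lists; filled points passed the limma test (red higher, blue lower), open points did not, and black bars are medians. The epicardial list has a median of -2.97 with 18 of 19 members lower, and the cardiomyocyte list a median of 1.72 with 18 of 20 higher.

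Cardiomyocyte genes rose: 18 of 20 were higher in the dKO pools and 0 lower (adjusted over the list alone, 20 higher), with a median log2 change of 1.72. The 4 members with the smallest p were sarcomere genes, with Mybpc3 rising from 376 ± 141 to 1401 ± 263 (log2 change 1.96), Myh7 from 1393 to 5375 (2.01), Actn2 from 373 to 1168 (1.72) and Ttn from 1331 to 4819 (1.89); the largest log2 change in the list was that of Nppa (2.33). Myl7 (0.81) and Nppb (1.22) did not pass. Camera gave an adjusted p of 4.56e-12 for the list, and adjusted p = 0.254 with an estimated correlation. The list medians per library were -0.73, 0.32 and 0.38 in controls and 1.83, 1.59 and 1.60 in dKO pools, with control 1 the lowest.

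Many glycolysis and cell cycle genes were also higher in the dKO pools. Of 18 glycolysis and hypoxia genes, 13 rose and 2 fell (the same counts adjusted over the list alone), with a median of 0.86. The glycolytic enzyme genes Pkm (396 to 843, log2 change 1.09), Pfkp (124 to 345, 1.50) and Hk1 (119 to 307, 1.39) rose, as did Bnip3 (89.4 to 186, 1.07), which acts in mitochondrial turnover. The hypoxia-responsive Car9 (-1.69) and Ndrg1 (-0.90) fell. Camera gave this list an adjusted p of 2.37e-05, and adjusted p = 0.254 with an estimated correlation. Of 22 cell cycle genes, 11 rose and 1 fell (the same counts adjusted over the list alone), with a median of 0.40. They included the mitotic genes Cenpf (104 to 185, 0.82) and Bub1 (54.5 to 91.0, 0.74), the cyclin Ccna2 (162 to 247, 0.61) and Rrm2, which supplies deoxynucleotides (110 to 183, 0.75); the thymidylate synthase gene Tyms fell by 0.50. Camera gave the cell cycle list an adjusted p of 0.000128, and adjusted p = 0.254 with an estimated correlation. The number of its members that rose was 5 to 8 in the fits that each left out 1 library. It was 7 without control 2, 6 without dKO 2 and 5 without dKO 3. With the number in the title as a block, a fit that leaves 1 residual degree of freedom, 0 rose. Tyms did not pass without control 4 or dKO 3.

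Mitochondrially encoded genes had a median of 0.86, but 1 of 13 passed (the same count adjusted over the list alone), mt-Co3, a subunit of cytochrome oxidase (1816 to 8525, log2 change 2.16). Camera gave an adjusted p of 0.000757, and adjusted p = 0.502 with an estimated correlation. Fry did not call the list (adjusted p = 0.142). The median was 0.58 with quantile normalization (camera adjusted p = 0.0112) and 0.28 without control 1 and dKO 1 together (camera adjusted p = 0.0482). Their medians per library were -0.59, 0.16 and 0.38 in controls and 1.45, 0.42 and 0.63 in dKO pools, and 2 members passed without control 4. With the cardiomyocyte score as a covariate, camera gave adjusted p of 0.112 for cell cycle (median 0.11), 0.324 for glycolysis (median 0.18) and 0.0848, in the opposite direction, for the mitochondrially encoded genes (median -0.55). Of 13 measured cyclin-dependent kinase inhibitor and p53 target genes, 1 fell (the same count adjusted over the list alone), the imprinted inhibitor Cdkn1c (621 to 184, -1.72). That list had a median of 0.23, a mean of -0.02 and an upward camera direction (adjusted p = 0.767).

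Mural genes, of smooth muscle and pericytes, were higher in the dKO pools for 9 of 14 measured members and lower for 0 (the same counts adjusted over the list alone), with a median log2 change of 0.83. The pericyte genes Rgs5 (170 to 340, log2 change 0.99), Abcc9 (138 to 328, 1.24) and Cspg4 (19.1 to 50.5, 1.41) and the smooth muscle gene Cnn1 (12.9 to 46.6, 1.81) rose. The 5 that did not pass were Tagln (0.35), Notch3 (0.34), Higd1b (0.22), Smtn (0.04) and Myh11 (-0.20). Camera gave an adjusted p of 1.74e-05, and adjusted p = 0.254 with an estimated correlation; it was 0.196, with a median of 0.096, with the cardiomyocyte score as a covariate.

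The lists of vascular genes differed in their medians, but no test compared these lists with one another. Which cells expressed their members was not measured. Pan-endothelial genes had a median log2 change of 0.02 and a mean of -0.03; 1 of 15 passed (the same count adjusted over the list alone), the angiopoietin receptor gene Tek, which fell from 214 to 113 (log2 change -0.91). Camera gave an adjusted p of 0.993 in the upward direction. Without control 1, 4 of its members were lower, and without control 1 and dKO 1 together 5 were (median -0.22, camera adjusted p = 0.0482). With the cardiomyocyte score as a covariate 2 of its 15 members were lower and 0 higher. Camera at the preset correlation then called the list downward (median -0.84, camera adjusted p = 2.87e-07). The correlation estimated for this list without the covariate was 0.74, far above the preset one, so that call is uncertain. Of 12 arterial genes, 8 rose and 0 fell (the same counts adjusted over the list alone), with a median of 1.23: besides Cxcr4, they included the Notch ligand gene Dll4 (7.42 to 25.7, 1.71), its target Hey1 (6.89 to 20.3, 1.43) and the netrin receptor gene Unc5b (52.97 to 113, 1.08). Gja4 (0.60), Sox17 (0.47), Efnb2 (0.06) and Jag1 (-0.12) did not pass. Camera gave the arterial list an adjusted p of 5.79e-06, and adjusted p = 0.157 with an estimated correlation; with the cardiomyocyte score as a covariate 2 members rose and the median was 0.92 (camera adjusted p = 9.93e-05).

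Of 6 venous genes, 4 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.89. Those that fell were the neuropilin gene Nrp2 (190 to 99.8, log2 change -0.92), the venous regulator Nr2f2 (81.6 to 44.0, -0.92), Flrt2 (272 to 143, -0.96) and the apelin receptor gene Aplnr (-0.87). Vwf rose from 11.8 to 23.1 (0.97, limma adjusted p = 0.017), and Ephb4 did not pass (-0.20). The rise of Vwf was lost without control 2, dKO 2 or dKO 3 (limma adjusted p = 0.0551, 0.0528 and 0.0668), and the fall of Flrt2 with no variance trend (limma adjusted p = 0.0611) and with the sex of the pools as a covariate (limma adjusted p = 0.0529). Camera did not call the venous list (adjusted p = 0.0557), but did so without control 1 (adjusted p = 0.0221), without dKO 1 (adjusted p = 0.0123) or without both (adjusted p = 0.00272), with quantile normalization (adjusted p = 0.0433), with library weights (adjusted p = 0.0183), and with the sex of the pools (adjusted p = 0.0191) or the cardiomyocyte score (adjusted p = 0.00955) as a covariate.

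Lymphatic endothelial genes had the lowest median of all lists, -3.02, with 6 of 8 lower and 1 higher (the same counts adjusted over the list alone). Besides Mmrn1 and Ccl21a, the hyaluronan receptor gene Lyve1 fell from 209 ± 43.5 to 17.0 ± 5.01 (log2 change -3.56), Reln from 51.2 to 3.86 (-3.42), the podoplanin gene Pdpn by 2.62 and the receptor gene Flt4 by 0.78 on the log2 scale. Pdpn is expressed by mesothelium as well. Itga9 rose by 1.11, and Prox1, the regulator of lymphatic identity, did not pass at 71.3 in control and 89.8 in dKO pools (0.35, limma adjusted p = 0.198). Which cells expressed Prox1 was not measured, so its total does not show whether its level in lymphatic cells changed. Camera gave the list an adjusted p of 0.000130, and adjusted p = 0.254 with an estimated correlation. Per library the list medians were -0.36, 0.10 and 0.28 in controls and -3.27, -3.003 and -2.65 in dKO pools.

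**Figure D3:**
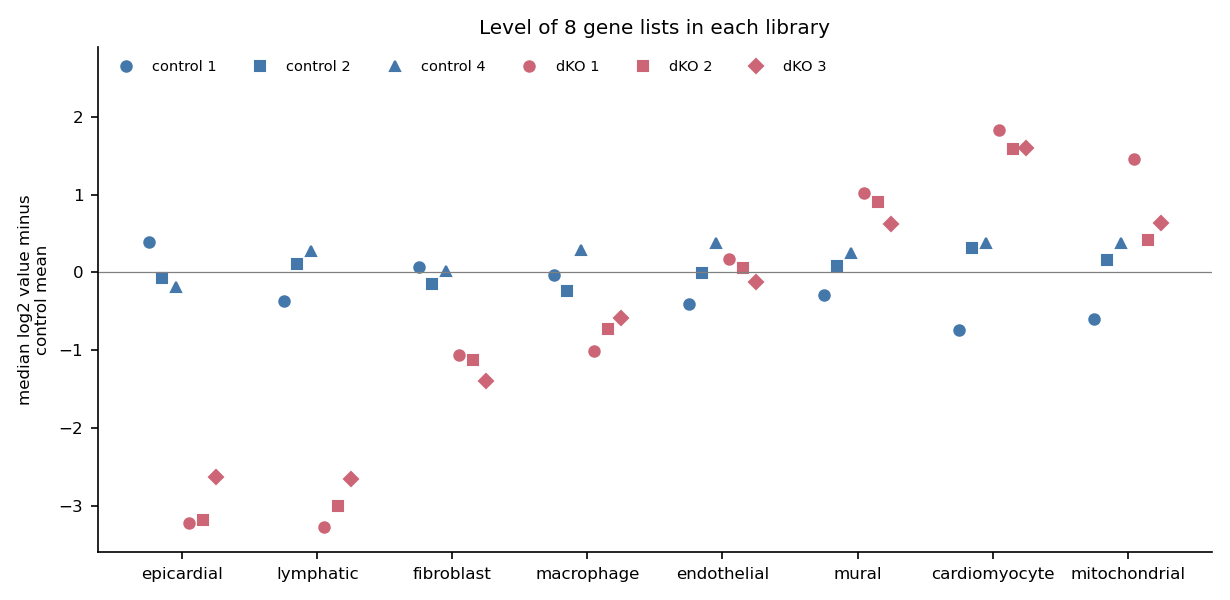
Median log2 value of 8 gene lists in each library relative to the control mean, with controls in blue and dKO pools in red. The epicardial and lymphatic medians lie at -2.64 or below in the 3 dKO pools and the cardiomyocyte medians at 1.59 or above, while the endothelial medians of the groups overlap.

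Angiogenic and growth factor ligands changed in both directions, 4 of 18 measured members upward and 6 downward (adjusted over the list alone, 5 and 7). The lymphangiogenic Vegfd fell from 47.4 to 3.13 (log2 change -3.54) and Angpt2 from 20.0 to 3.78 (-2.13), while Cxcl12 rose from 53.6 to 153 (1.52) and Vegfa from 102 to 209 (1.02). The list had a median of 0.08, a mean of -0.24 and a downward camera direction (adjusted p = 0.825). Without dKO 1, 2 members rose and 3 fell, and without dKO 2, 3 fell.

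Of 12 measured retinoic acid genes, 8 fell and 1 rose (adjusted over the list alone, 9 and 1), with a median log2 change of -1.09. Enzymes of retinoic acid synthesis fell, with Aldh1a2 going from 214 to 36.2 (log2 change -2.49), Aldh1a1 from 100.1 to 14.7 (-2.60) and Rdh10 from 39.2 to 13.2 (-1.50), and so did the degrading enzyme Cyp26b1 (10.05 to 0.814, -2.58). Cyp26a1, another degrading enzyme, rose by 1.03, a call lost when any 1 library was left out and with edgeR (adjusted p = 0.111). Rarb (-0.60), Rara (0.46) and Rxra (-0.27), which encode receptors, did not pass. Camera gave the list an adjusted p of 7.70e-05, and adjusted p = 0.157 with an estimated correlation; with the cardiomyocyte score as a covariate 1 member fell and the median was -0.90 (camera adjusted p = 0.00159). Aldh1a2 is also a member of the epicardial list.

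Of 20 measured Wnt pathway genes, 8 fell and 1 rose (adjusted over the list alone, 10 and 4), with a median of -0.65. Besides Rspo1, these included Wnt2b (43.6 to 3.93, log2 change -3.09), the secreted Wnt antagonist gene Sfrp2 (190 to 53.7, -1.82) and the receptor gene Fzd7 (58.4 to 15.8, -1.79). Wnt4 rose by 1.03, but passed in none of the fits without control 2, control 4, dKO 1, dKO 2 or dKO 3. Camera gave the Wnt list an adjusted p of 0.00188, and adjusted p = 0.270 with an estimated correlation. Of 17 measured FGF pathway genes, 6 fell and 0 rose (the same counts adjusted over the list alone), with a median of -0.36; 1 rose without control 1. The ligand gene Fgf2 fell from 77.3 to 17.9 (-2.02), the feedback inhibitor gene Spry1 from 61.9 to 28.6 (-1.12), and the receptor genes Fgfr2 (-1.24) and Fgfr1 (-0.69) fell too. Camera gave the FGF list an adjusted p of 0.0141, and adjusted p = 0.254 with an estimated correlation. With the cardiomyocyte score as a covariate, camera gave adjusted p of 0.364 for Wnt (median -0.12) and 0.514 for FGF (median -0.29).

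Of 22 measured TGF-beta and BMP genes, 6 fell and 3 rose (adjusted over the list alone, 7 and 3), with a median of -0.22. The ligand gene Bmp6 fell from 96.7 to 9.56 (log2 change -3.22), Bmp4 from 37.6 to 17.1 (-1.10) and the receptor gene Tgfbr2 from 187 to 98.3 (-0.93), while Bmp7 rose from 25.3 to 65.3 (1.38). Camera did not call this list (adjusted p = 0.0793), but did so without dKO 1 (adjusted p = 0.0386).

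Axon guidance ligands and receptors changed in both directions, 14 of 26 measured members downward and 7 upward (adjusted over the list alone, 16 and 7), with a median log2 change of -0.88. The semaphorin gene Sema3d, also an epicardial marker, fell from 428 to 56.1 (log2 change -2.89), the Slit ligand genes Slit2 from 150 to 38.0 (-1.96) and Slit3 from 42.5 to 6.88 (-2.41), and the receptor gene Plxna4 from 222 to 54.9 (-2.001). Camera gave an adjusted p of 0.00781, and adjusted p = 0.283 with an estimated correlation; it was 0.582, with a median of -0.18, with the cardiomyocyte score as a covariate. The neuronal list has 22 genes, of which 8 were measured. Of these, 3 rose and 1 fell (adjusted over the list alone, 3 and 3). Ddc, an enzyme of catecholamine synthesis (32.9 to 117, 1.82), Uchl1 (13.8 to 27.9, 0.96) and Hand2 (16.7 to 35.9, 1.12) rose. The growth cone gene Gap43 fell (28.3 to 14.6, -0.92). Hand2 is also in the cardiac transcription factor list. With the cardiomyocyte score as a covariate its change was -0.27 (limma adjusted p = 0.837). Which cells expressed these genes was not measured. Camera gave the neuronal list, with a median of 0.05, an adjusted p of 0.599. Of 6 measured Schwann cell genes, 2 fell (adjusted over the list alone, 2 lower and 1 higher), Mbp (48.9 to 7.63, -2.54) and Cdh19 (2.28 to 0.0555, -1.61, and -6.33 with edgeR, resting on 0, 1 and 0 reads in dKO pools), with a median of -0.52 and a camera adjusted p of 0.0793. Without control 2, 1 Schwann cell gene rose.

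Cardiac and epicardial transcription factors split, with 6 of 23 measured members higher and 5 lower (adjusted over the list alone, 8 and 5). Tbx20, a regulator of cardiomyocytes, rose from 249 to 629 (log2 change 1.35), while Klf4 fell from 61.4 to 13.8 (-2.13), Sox6 from 48.1 to 16.7 (-1.45) and Osr1 from 43.1 to 1.92 (-3.65). Osr1 was 83.0 in control 1 against 22.9 and 23.4 in the other controls. The list had a median of 0.34, a mean of -0.04 and an upward camera direction (adjusted p = 0.400). Of 16 measured TALE and Hox genes other than the targets, 1 rose and 1 fell (the same counts adjusted over the list alone), with a median of -0.39 and a camera adjusted p of 0.197. Pknox2 rose from 4.14 to 13.7 (1.63) and Hoxa2 fell from 4.13 to 0.408 (-1.69, limma adjusted p = 0.0201, and -3.45 with edgeR). Hoxa2 was 8.12 in control 1 against 2.07 and 2.19 in the other controls, and its log2 change was -1.04 without control 1 and dKO 1. The fall of Hoxa2 was lost without dKO 1 (limma adjusted p = 0.0582), dKO 3 (0.0588) or control 1 and dKO 1 together (0.0708), with the sex of the pools as a covariate (0.0554) and with voom (0.0528), and 2 members fell without control 1 and without control 2.

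Macrophage and leukocyte genes were lower for 8 of 15 members and higher for 0 (adjusted over the list alone, 9 lower), with a median log2 change of -0.82. The mannose receptor gene Mrc1 fell from 178 to 56.1 (log2 change -1.62), F13a1 from 212 to 55.0 (-1.92), the chemokine gene Pf4 from 26.0 to 5.001 (-2.14) and the receptor gene Csf1r from 114 to 53.2 (-1.10). Camera gave an adjusted p of 9.99e-06, and adjusted p = 0.280 with an estimated correlation; with the cardiomyocyte score as a covariate 2 members fell and the median was -0.82 (camera adjusted p = 0.00116). Of 9 measured interferon genes, 2 fell (the same count adjusted over the list alone), Irf1 (28.2 to 11.6, -1.21) and Ifi27 (30.2 to 12.4, -1.22), with a median of -0.27 and a camera adjusted p of 0.133. Of 14 immediate early and stress genes, 1 fell (0 adjusted over the list alone), Btg2 (49.1 to 32.8, -0.55, limma adjusted p = 0.0388), with a median of -0.16 and a camera adjusted p of 0.530. Btg2 did not pass without control 1, control 2, dKO 2 or dKO 3 (limma adjusted p = 0.109, 0.0687, 0.121 and 0.122), with no variance trend (0.0783) or with the sex of the pools as a covariate (0.0969), and without dKO 1, 3 members fell and camera called the list (adjusted p = 0.0335).

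Of 8 measured erythroid genes, 0 passed in limma, edgeR, DESeq2 or adjusted over the list alone (1 at an unadjusted limma p under 0.05); the globin genes Hbb-bs (788 to 914, log2 change 0.28, limma adjusted p = 0.516) and Hba-a1 (450.0 to 483, 0.19, limma adjusted p = 0.656) were the most abundant. The erythroid list had a median of 0.29 (camera adjusted p = 0.166) but was called without control 1 (camera adjusted p = 0.00368, with 3 members higher) and without dKO 2 (camera adjusted p = 0.0340, with 2 higher). Of 20 genes of liver, lung, thymus, skeletal muscle and fat, 1 was measured, skeletal actin Acta1, which the fetal heart also expresses (8.22 to 17.3, log2 change 1.11, limma adjusted p = 0.029; 1 higher adjusted over the list alone). Its call was lost with edgeR (adjusted p = 0.0585), with no variance trend (limma adjusted p = 0.0537) and without control 1, control 4, dKO 1, dKO 2 or dKO 3 (limma adjusted p = 0.0692, 0.0924, 0.0739, 0.0702 and 0.0805). Of 5 sex-linked genes, 0 passed in limma, edgeR, DESeq2 or adjusted over the list alone (0 at an unadjusted limma p under 0.05), with a median of 1.68 (camera adjusted p = 0.567). Among them, Xist had group means of 510 and 351 (-2.47, limma adjusted p = 0.555, and -0.54 with edgeR) and Eif2s3y of 32.1 and 49.8 (1.93, limma adjusted p = 0.513, and 0.63 with edgeR).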

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

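The alternatives using 2 libraries per group, the cardiomyocyte score, the sex of the pools, mitochondrial gene removal, log2 of the deposited values and voom were tests chosen only after the results were seen. Scaling, pseudocount, filter, variance, library weight and tool choices left the count of 3205 genes within 2711 to 3813, and Meis2 past the threshold. The filter at 1 removed no gene, so leaving it out tests nothing. Of named gene results over all alternatives, 2423 kept direction and side of the threshold, 103 lost and 7 gained the call, and 13 changed sign; of list tests 632 kept both, 25 lost and 21 gained the call in the same direction, and 21 changed direction. Leaving out each library gave 2167 to 2725 genes (higher 898 to 1262, lower 1269 to 1545), 15 to 18 lists and log2 changes of -1.05 to -0.79 for Meis2. A threshold of 0.01 gave 1627 genes (643 higher, 984 lower) and a 2-fold minimum 1595 (603 and 992), by their stricter construction.

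Using the shared numbers as a replicate block gave 1360 genes (580 higher, 780 lower). This leaves 1 residual degree of freedom, so that the lower count follows from the construction, and nothing shows that the numbers pair the pools: deviations from the group mean correlated at -0.18 for the pools numbered 1 and -0.20 for those numbered 2 (across genes, which are not independent). The pools sharing a number also differ in sex.

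With the cardiomyocyte score as a covariate, 285 genes (60 higher, 225 lower), 32 of 99 named gene entries, 46 of 211 list member calls and 10 lists (3 higher) passed. The score separates the genotypes without overlap, so this fit shares the contrast with the covariate and has wide errors (the median SE over the list members went from 0.23 to 0.44). Meis2 was -0.65 (limma adjusted p = 0.504, against 1.7e-05 to 0.0184 in its other alternatives). Flrt2 (0.0699), Hand2 (-0.27), Hoxa2 (0.61) and Btg2 (0.0088) changed sign without passing, as did Meis1 (0.92), Xist (5.71), Eif2s3y (-3.98), and the mitochondrially encoded (camera adjusted p = 0.0848) and sex-linked (0.619) lists; the cause was not tested further. The sex of the pools as a covariate gave 2384 genes, 2339 of them shared with the 3205, and 17 lists.

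For lists, camera with an estimated correlation called 0 (0 higher, 0 lower, against 15 with the preset), its smallest adjusted p being 0.157; fry called 19, 5 higher and 14 lower. Without control 1 and dKO 1, 19 lists were called. With the cardiomyocyte score as a covariate the venous (camera adjusted p = 0.00955) and erythroid (3.64e-06, higher) lists were called, and the TALE and Hox (0.0449) and endothelial (2.87e-07) lists were called in the direction opposite to the uncalled main result. With the sex of the pools the venous (camera adjusted p = 0.0191) and erythroid (0.0324) lists were called. At 0.0487 to 0.0740 per read, depth limits the folds of genes with few reads in 1 group, such as Ccl21a, Nupr1 and Cdh19, and 2-fold changes were recovered less often than 4-fold ones on simulated data (41% and 72%).

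Other changes of sign were of results that did not pass in either fit, except the endothelial list without control 1 and dKO 1 (camera adjusted p = 0.0482); the cause was not tested. Without those libraries Meis1 was 0.13, Xist 0.39 and Eif2s3y -0.36; with the sex of the pools Xist was 0.52 and Eif2s3y -0.18; with library weights Xist was 0.12; with the replicate block Hba-a1 was -0.13. Leaving out each library gave -0.32 to 0.0453 for Meis1 and -0.0442 to 0.55 for Hba-a1. The endothelial list changed direction with quantile normalization (camera adjusted p = 0.840), the filter at 5 (0.967), library weights (0.349), the sex of the pools (0.410), log2 of the deposited values (0.99985) and voom (0.994), and with fry (0.803). The kinase inhibitor list did so with the filter at 5 (0.967), fry (0.803) and the replicate block (0.818), and the sex-linked list with the sex of the pools (0.928). Among the fits leaving out a library, the endothelial list did so without control 1 (0.149), dKO 1 (0.793) and dKO 2 (0.982), the kinase inhibitor list without control 4 (0.977, range 0.542 to 0.977) and the immediate early list without dKO 2 (0.932, range 0.0335 to 0.932).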

Other observations

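Gene groups assembled after looking at the top of the gene ranking, and the tests of them, were chosen only after those results were seen, as were the 4 tests of tissue composition, the 2 of the sex of the pools and the edgeR comparisons of mast cell with macrophage genes; the counts of other splits were planned. For the 5 added groups, the prediction was written before the values of the members called unseen here were looked at. Mast cell genes were lower for 9 of 12 measured members and higher for 0, with a median log2 change of -2.42. Besides Cpa3 and Cma1, they included the tryptase gene Tpsb2 (28.8 to 0.620, log2 change -4.23), the histamine-forming enzyme Hdc (64.5 to 2.52, -4.31) and the receptor gene Il1rl1 (28.1 to 3.28, -2.77). Kit (0.41), Gata2 (-0.19) and Slc18a2 (-0.51) did not pass. Kit was nonetheless higher in each dKO pool (47.5 to 56.2) than in any control (32.5 to 44.7). Which cells expressed the members that fell, and those that did not, was not measured. Imprinted genes of the growth network were lower for 16 of 23 measured members, including Dlk1 (363 to 44.7, -3.02), the noncoding Rian (1528 to 393, -1.94), H19 (-0.97) and Igf2 (-0.82), and 1 was higher, Igf2r (639 to 1186, 0.89). Complement components and regulators were lower for 9 of 17, including the inhibitor gene Serping1 (192 to 35.1, -2.42), C1ra (26.1 to 0.285, -4.38, and -6.71 with edgeR), C2 (43.1 to 1.76, -3.89) and the regulator Cd55 (93.9 to 11.2, -3.03); the macrophage list holds 3 of the 17. C2 was 73.0 in control 1 against 26.2 and 30.1 in the other controls, and Hdc was 4.21 in dKO 3 against 0.653 and 2.70 in the other dKO pools. Other genes share 62.8% of the exonic bases of Igf2 and 42.8% of those of C2.

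Nuclear-encoded respiratory chain genes were higher for 31 of 35, such as the complex I gene Ndufv1 (70.7 to 173, log2 change 1.3001), with a median of 0.87. The cardiomyocyte list moved with them (18 of 20 higher, median 1.72). When the cardiomyocyte score was a covariate, 0 of the 35 were higher in limma. At an unadjusted limma p under 0.05, 0 were higher and 3 lower. The median was then -0.23, with a median SE of 0.30 against 0.21 before. The trend with the score rested largely on control 1, so this fit does not show that myocardium accounts for the rise. With the sex of the pools as a covariate 20 were higher (median 0.82). With the score 4 imprinted genes were lower (median -0.51 against -1.08 before), 4 complement genes (-0.99 in both fits) and 4 mast cell genes (-2.26 against -2.42). Basement membrane genes split: the collagen IV genes Col4a4 (39.6 to 1.06, -4.30) and Col4a3 (22.0 to 0.548, -3.89), Npnt (169 to 15.2, -3.33) and Lama3 (45.7 to 5.47, -2.87) were among 8 of 24 that fell, and Frem1 (1.25) and Hspg2 (0.75) were among those that rose.

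On the unseen members, the hypothesis that imprinted growth genes are lower as a group had a median log2 change of -1.17, with 13 of 20 lower and 1 higher (limma camera with an estimated correlation, Benjamini-Hochberg adjusted p = 0.0542 over the 5 groups). For complement the median was -0.99, with 5 of 11 lower (limma camera adjusted p = 0.0785, computed the same way). For the respiratory chain it was 0.87 (limma camera adjusted p = 0.241), which leaves the hypothesis open. For basement membrane it was 0.23, with 6 of 22 lower and 3 higher (limma camera adjusted p = 0.974), which argues against a fall of the group. The predictions for imprinted and complement genes had set a bound of 0.05 on the unadjusted p, which both met, but none of the 5 groups passed after adjustment.

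In the dKO pools the epicardial list fell and the cardiomyocyte list rose; a smaller share of the epicardial layer alone would raise all other cell types alike, but the cardiomyocyte median exceeded the endothelial median by 1.69 on the log2 scale, against 0.43 for the summed interquartile ranges of both lists divided by 2, which argues against it as the whole cause. When the cardiomyocyte score was a covariate, the epicardial median was -2.41 (interquartile range 1.38) against -2.97 (0.81) before. Members lower went from 18 to 11 as the median SE rose from 0.24 to 0.42. The cardiomyocyte median was 0.02, which follows from the construction, since the score is the mean of that list. The trend was fitted within the groups. There control 1 (score 6.81) lay far from controls 2 and 4 (7.92 and 7.97), while the dKO pools ran from 9.12 to 9.44. The trend thus rests largely on 1 library, so this fit does not decide whether a linear trend with the score is the whole cause of the epicardial fall. More myocardium in the dKO dissections may account for the cardiomyocyte rise: its members have an SD of 0.31, against a median of 0.39 in 10000 random lists of risen genes, but at percentile 10.7, so the spread does not decide. For the epicardial fall, dilution by myocardium stays open, whether or not it is linear in the score. An interquartile range 3.80 times that of the cardiomyocyte list and the endothelial median of 0.02 do not exclude it. The level of epicardial genes in myocardium was not measured, and myocardium holds endothelium of its own. With the sex of the pools as a covariate, Xist went from -2.47 to 0.52. The epicardial median was then -2.84 (interquartile range 0.70) and the cardiomyocyte median 1.56 (0.26). Both lists passed camera at the preset correlation, but without the covariate neither passed with an estimated correlation (camera adjusted p = 0.157 and 0.254). Both medians exceeded their interquartile ranges, which measure how members differ and not the spread between pools. Where Ddx3y exceeded Xist, epicardial list medians were -0.18 in control 4 and -3.22 and -3.19 in dKO 1 and 2. In the other pools they were 0.39 and -0.07 in controls 1 and 2 and -2.64 in dKO 3. Cardiomyocyte medians were 0.38 against 1.83 and 1.59, and -0.73 and 0.32 against 1.60. The genotypes thus differed in the same direction in both kinds of pool, which argues against sex as the whole cause of either change. A response of expression to loss of the Meis genes, the difference the design names, stays open.

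Fewer mast cells in the dKO tissue could underlie the fall of their genes: the 7 unseen members had a median of -1.47, with 5 of 7 lower (limma camera with an estimated correlation, Benjamini-Hochberg adjusted p = 0.0785), and a median of -2.33 with edgeR, which does not add 1 to the values. Dilution of all leukocytes alike would lower both lists by 1 factor. Over all 12 measured members, the edgeR median lay -3.02 from that of the macrophage list (-3.88 against -0.86). That is beyond the 2.34 of the summed interquartile ranges of both lists divided by 2 (two-sided permutation p = 0.0008 across genes, 100000 resamples). The 12 include seen members whose large falls prompted the group, so this distance does not decide. Slc18a2, seen as a member of the neuronal list, did not pass (-0.51). For the unseen members alone the distance was -1.48 with edgeR (permutation p = 0.0173). On the scale of log2 of the value plus 1 it was -1.60 for all members (permutation p = 0.00159) and -0.65 for the unseen ones (permutation p = 0.117). These 3 distances lay within the spread of the lists, so dilution of all leukocytes alike stays open. The tryptase genes Tpsb2 and Tpsab1 are close copies that can share reads, and 1 of the 12 genes, Slc18a2, is also in the neuronal list. A lower output of these genes per cell was not tested.

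Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes as the 3205 observed, and the highest of the others gave 5. For lists, 1 split, again the real one, gave as many as 15, and the others gave 5 to 10. Every other split mixes the genotypes unevenly in both of its groups. The genotype difference then enters the spread within groups, so few gene calls follow from the construction. Camera at the preset correlation still called 5 to 10 lists where at most 5 genes were called. Uneven genotypes and too low a preset correlation cannot be told apart here, so the 15 list calls are uncertain. With 10 splits the share cannot fall under 0.05.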
